A study of Mus musculus with 7 samples.

How the data were processed

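The deposited table gave whole-number counts per gene for 7 libraries of adult mouse left atria, 4 labelled FOG2 overexpression and 3 labelled wild type. Per the submitters' processing notes, the authors' tools included STAR, HTSeq 0.6.0 and DESeq2 with the mm10 build, with no roles stated; the deposited values are counts as HTSeq writes them, with its summary rows. Per the labels' protocols, RNA was isolated from atria homogenised in TRIzol and libraries were made with an Illumina kit; one label calls the libraries polyA mRNA sequencing while the protocol names removal of ribosomal RNA, so the selection step is uncertain. The strand setting of the counting, and the versions of STAR and DESeq2, are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart, and near-identical copies share or lose reads because reads with several alignments were counted apart. The labels do not give sex, litter or batch, and do not say that each library is a separate animal, so p-values measure the spread between these libraries, which may be partly technical.

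Of all reads in the table, 27.8% to 33.1% per library lay in rows naming a gene. Rows naming no gene were left out of library sizes and tests: 23.4% to 30.5% had no feature, 37.1% to 43.4% aligned to several places and 0.101% to 0.254% were ambiguous. The 24421 gene rows summed to 5562520 to 8655655 per library, and 1 count stood for 0.111 to 0.174 CPM. All 7 columns of the table were mapped to samples by their names. The 5 haemoglobin genes on the erythroid list were at 0 in every library, and mitochondrially encoded genes were not analysed here.

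Genes were filtered with filterByExpr by group (minimum count 10, minimum total 15), which left 13295, scaled with TMM and tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust dispersions, two-sided, with no covariate. The Benjamini-Hochberg adjusted p was taken over all tested genes with a threshold of 0.05. Standard errors are the absolute log2 fold change over the root of the F statistic. CPM values use the TMM-scaled totals, and log2 CPM a prior count of 2. The common biological coefficient of variation was 0.188. Where a group held 0 counts of a gene, the fold is a bound against 3 counts over the group, and with 1 to 3 counts the ratio has a 95% counting interval; both cover counting error only.

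Of 50 gene lists, camera (limma 3.58.1) tested the 43 with at least 5 tested members with its preset correlation of 0.01, adjusted over lists, and again with an estimated correlation, with fry beside it. The lists, groups, test and alternatives were fixed before the data were examined. The genes named are Zfpm2; the 10 higher and 10 lower genes with the largest fold changes among called genes with a mean CPM of at least 1, groups that did not overlap and a full gene name; the 5 higher and 5 lower with the smallest p at that level; 15 genes of atrial rhythm and stress fixed by name; and up to 4 members with the smallest p of each list. Some genes that this rule names are not reported here, with a test of replicate 1 that rested on them; they stayed in the counts. Counts of list members include genes that the text does not name. Gene positions, lengths and GC content came from the GENCODE M21 annotation by symbol, which matched 98.5% of the table's symbols.

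The alternatives were other scalings (RLE, library totals only, upper quartile), no filter, a CPM of at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom, a fit without robust dispersions, the replicate number as a block, 1 surrogate variable from sva 3.50.0, the level of Y-linked transcripts as a covariate, totals without the 10 most abundant genes, and each library left out in turn. Chosen after seeing the data were the female libraries only, scaling to the sarcomere list, and an offset for transcript length and GC content. On simulated counts with 200 changed genes among 13137, the test made 123 calls, of which 10 were false and 0 had the wrong sign; it recovered 20.9% of 1.5-fold, 55.2% of 2-fold and 93.9% of 4-fold changes.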

Results

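RNA sequencing measured transcripts in the left atria of adult CD1 mice, an outbred strain. The labels give 4 libraries from atria overexpressing FOG2 and 3 from wild type atria, all from animals kept without doxycycline for 1 week. FOG2, the product of Zfpm2, is a zinc finger cofactor that binds GATA transcription factors. The title of the series names TBX5, GATA4 and an atrial gene network tied to atrial fibrillation risk, so the comparison asks which atrial transcripts differed when FOG2 was overexpressed. Reads counted to genes came to 8521897, 7673309 and 8579443 in the wild type libraries and to 8655655, 6448260, 5562520 and 8610508 in the overexpression libraries. A single read stood for 0.111 to 0.174 CPM, counts scaled to the library's gene total. Wild type libraries correlated with each other at r = 0.977 to 0.983 across genes, as did overexpression replicates 2, 3 and 4 at 0.978 to 0.983, while overexpression replicate 1 correlated with those 3 at 0.947 to 0.949.

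**Figure D1:**
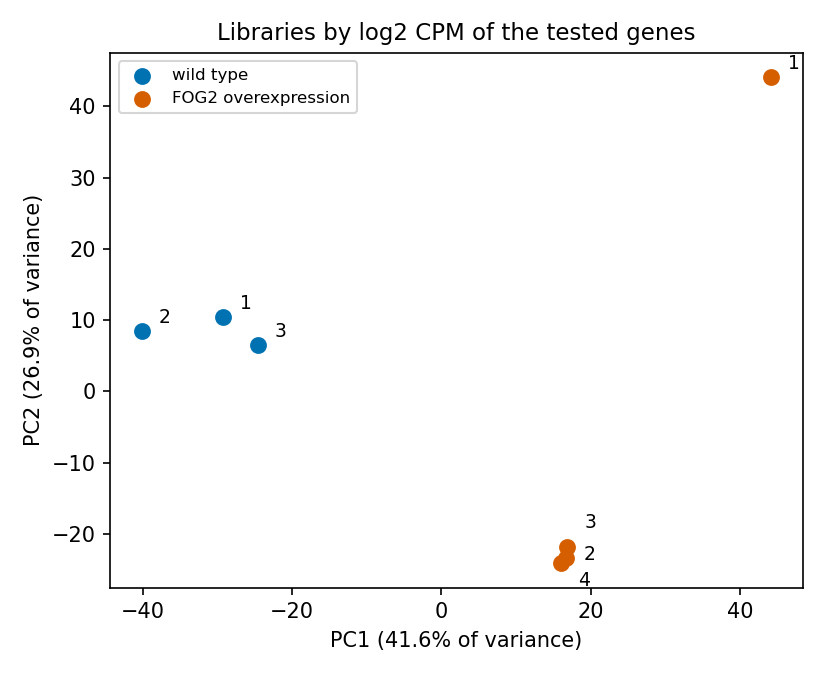
Principal components of log2 CPM over the tested genes, one point per library with its replicate number, 3 wild type (blue) and 4 FOG2 overexpression (orange). The first component held 41.6% of the variance and separated the groups, and the second, with 26.9%, set overexpression replicate 1 at 44.1 apart from the other 3 overexpression libraries at -24.1 to -21.8.

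Zfpm2 was higher in every overexpression library. Its mean was 218 ± 54.2 CPM (SD, n = 4) against 30.7 ± 1.16 CPM (SD, n = 3) in wild type, a 7.08-fold difference with a log2 fold change of 2.82 ± 0.22 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.05e-04). The overexpression libraries held 140.1, 222, 262 and 246 CPM in replicates 1 to 4. In the mm10 annotation, the gene lies on the plus strand of chromosome 15 from 40655035 to 41104592. Counts per gene do not separate transcripts of a transgene from those of the mouse's own locus.

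Dkk3 and Kcnj3 were among the genes that fell in atria overexpressing FOG2, and Acta2 among those that rose. Of 13295 genes tested, 206 were higher and 438 lower at an adjusted p under 0.05, and 313 of these differed at least 2-fold, 119 higher and 194 lower. Dkk3, a secreted glycoprotein, fell from 939 ± 35.8 to 58.05 ± 7.21 CPM (log2 fold change -4.02 ± 0.13, SE, adjusted p = 9.21e-07). Acta2, smooth muscle actin, rose from 24.1 ± 10.8 to 798 ± 161 CPM (5.05 ± 0.33, adjusted p = 1.37e-04). At an unadjusted p under 0.05 there were 2551 genes, and the groups did not overlap in 19.8% of the tested genes, where chance alone gives 5.71%. Without overexpression replicate 1, the library that stood apart, 493 genes were higher and 658 lower, and these held 640 of the 644 genes called with it. The counts also moved without other libraries, to 78 higher and 205 lower without wild type replicate 1, 75 and 181 without wild type replicate 2, 133 and 263 without wild type replicate 3, 149 and 283 without overexpression replicate 2, 139 and 291 without replicate 3, and 125 and 304 without replicate 4. Genes changed at least 2-fold numbered 198 and 184 without wild type replicates 1 and 2. Of the calls without wild type replicates 1, 2 and 3, 275 of 283, 254 of 256 and 354 of 396 were also called with every library. Without overexpression replicates 2, 3 and 4 these were 398 of 432, 397 of 430 and 409 of 429. A fit with 1 library fewer has less power, so a call lost there need not have rested on that library. The split by direction depended on scaling: with library totals only, 444 genes were higher and 294 lower (60.2% higher against 32.0%), and the median log2 fold change of all genes moved from 0.02 to 0.15. Scaled to the sarcomere list, a scaling added after the data were seen, 2508 were higher and 215 lower (92.1% higher) with that median at 0.39. Counts of list members called higher with that scaling, given below, are to be read against those 2508 of all 13295 genes.

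**Figure D2:**
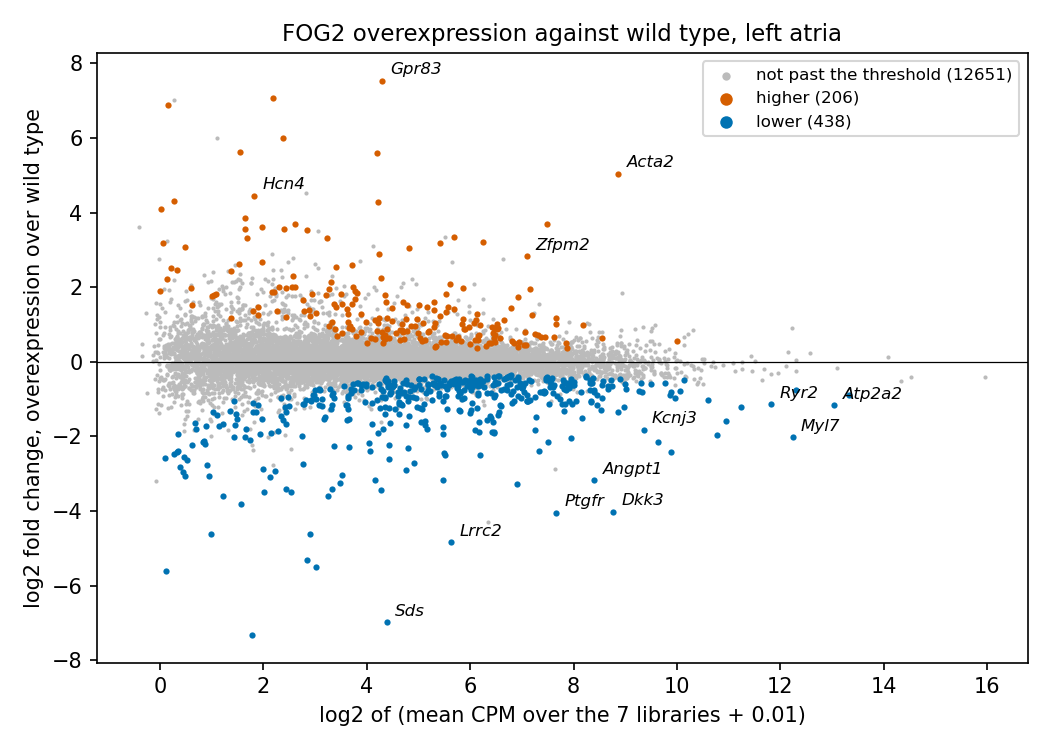
Log2 fold change of FOG2 overexpression over wild type against the log2 of the mean CPM over the 7 libraries, one point per tested gene. Orange points are the 206 genes called higher, blue the 438 called lower and grey those not past an adjusted p of 0.05.

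Within the atrial rhythm network, 9 of 28 measured genes fell, 0 rose and 19 did not pass the test, with a median log2 fold change of -0.43. With libraries scaled to the sarcomere list, which takes out a decrease shared with the sarcomere genes, that median was -0.08 (4 higher and 8 lower). Adjusted over the list alone, the counts were 1 higher and 10 lower, the higher gene being Kcnh2 (0.64 ± 0.19). Besides Dkk3, the genes that fell included Kcnj3, a subunit of the acetylcholine-activated potassium channel, from 1109 ± 81.00 to 314 ± 46.3 CPM (-1.82 ± 0.14, adjusted p = 1.80e-04), and Sln, the atrial regulator sarcolipin (-1.58 ± 0.15, adjusted p = 6.10e-04). The list was lower than other genes with camera's preset correlation (adjusted p = 1.35e-18). It had an adjusted p = 0.190 with an estimated correlation, and 0.00963 by fry. The rhythm network had 1 higher and 8 lower without overexpression replicate 2 or with library totals only. Among the sodium channel and gap junction genes, 8 of 25 fell and 0 rose (0 higher and 10 lower adjusted over the list alone). Scn10a (-3.42 ± 0.28), Scn4b (-3.03 ± 0.40) and Fgf13, which binds sodium channels (-1.24 ± 0.13), fell. That list's adjusted p was 2.84e-10 with the preset correlation, and it had an adjusted p = 0.190 with an estimated correlation. Its median of -0.20 became 0.16 (3 higher and 7 lower) with libraries scaled to the sarcomere list. The sodium channel list had 0 higher and 4 lower without wild type replicate 2.

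Calcium handling genes fell in 8 of 31 cases and rose in 0 (5 higher and 11 lower adjusted over the list alone). Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell from 12385 ± 1293 to 5502 ± 1138 CPM (-1.17 ± 0.18, adjusted p = 0.00661), and Ryr2, its calcium release channel, from 5237 ± 643 to 2385 ± 427 CPM (-1.13 ± 0.17, adjusted p = 0.00549). Pln, the inhibitor of the pump (-1.21 ± 0.15), and the channel subunit Cacna2d2 (-2.28 ± 0.30) fell. As a list, these genes were lower with the preset correlation (adjusted p = 0.00333) and had an adjusted p = 0.379 with an estimated correlation. The median of -0.13 became 0.24 (11 higher and 6 lower) when scaled to the sarcomere list and -0.00551 with library totals only. The calcium handling list had 0 higher and 5 lower without wild type replicate 2, 5 and 10 without overexpression replicate 1, 1 and 7 without overexpression replicate 4, and 4 and 7 with library totals only. Without overexpression replicate 1 the preset adjusted p was 0.0590. Potassium and pacemaker channels went both ways, with 2 of 28 higher and 5 lower (4 higher and 7 lower adjusted over the list alone), and the list was not called (adjusted p = 0.151). The potassium channel list had 2 higher and 3 lower without wild type replicates 1 or 2, 3 and 8 without overexpression replicate 1, 3 and 3 without overexpression replicate 2, and 4 and 4 with library totals only. Kcnip2 (-1.68 ± 0.24) and Kcna4 (-1.07 ± 0.15) fell. Hcn4, a pacemaker channel, rose from 0.269 ± 0.256 to 5.996 ± 1.32 CPM (4.45 ± 0.49, adjusted p = 0.00110).

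**Figure D3:**
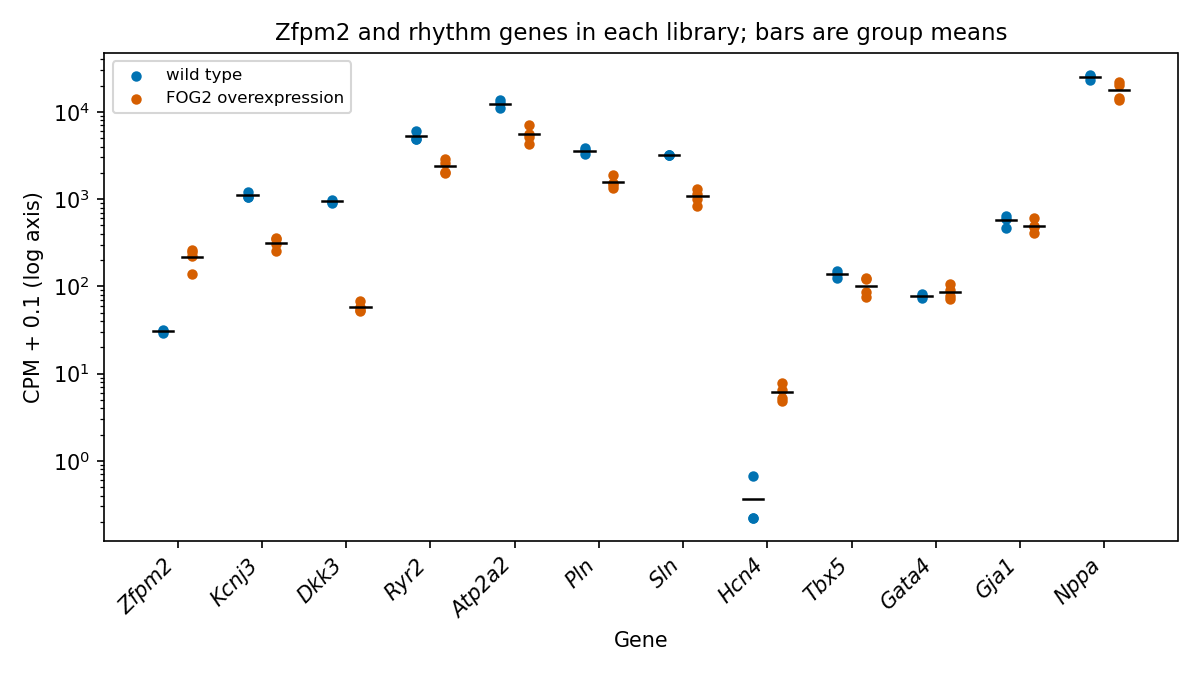
CPM plus 0.1 on a log axis for Zfpm2 and 11 other genes, one point per library (3 wild type in blue, 4 FOG2 overexpression in orange), with bars at group means. Kcnj3, Dkk3, Ryr2, Atp2a2, Pln and Sln lay below every wild type library in all 4 overexpression libraries, and Zfpm2 and Hcn4 above. Tbx5 and Nppa also lay below in all 4, though neither passed the test. Gata4 and Gja1 overlapped.

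The factors named beside FOG2 in the series did not pass the test. Tbx5 had 139 ± 11.8 CPM in wild type and 102 ± 24.1 in overexpression (-0.45 ± 0.18, adjusted p = 0.207), and Gata4 77.2 ± 4.40 and 86.6 ± 15.6 (0.16 ± 0.14, adjusted p = 0.563). Gata6 and Nkx2-5 had log2 fold changes of 0.24 ± 0.16 and 0.27 ± 0.22, and the connexin genes Gja1 and Gja5 of -0.20 ± 0.16 and -1.07 ± 0.41. Nppa, the atrial natriuretic peptide, stood at -0.51 ± 0.20 (adjusted p = 0.196), and the myosin heavy chains Myh6 and Myh7 at -0.40 ± 0.19 and -0.38 ± 0.19. Nppb had 394 ± 10.8 CPM in wild type and 168, 19.6, 6.96 and 15.8 CPM in overexpression replicates 1 to 4 (-2.88 ± 0.97, adjusted p = 0.163). Without replicate 1 its adjusted p was 8.24e-05. Among the cardiac transcription factors, 1 of 27 rose and 0 fell (1 higher and 0 lower adjusted over the list alone). The gene that rose was Hand2 (0.65 ± 0.13, adjusted p = 0.0235), whose adjusted p was 0.121 without wild type replicate 1, 0.123 without wild type replicate 2, 0.0668 without overexpression replicate 4, 0.108 with the replicate block and 0.0585 in the female libraries. The transcription factor list had 0 higher and 0 lower without wild type replicates 1 or 2 or overexpression replicate 4, and 2 and 0 with library totals only. Genes at atrial fibrillation loci, a list that shares members with the rhythm network, went both ways, with 3 of 38 higher and 5 lower (5 higher and 8 lower adjusted over the list alone) and a median of -0.12 that became 0.00 with library totals only and 0.24 (10 higher and 3 lower) when scaled to the sarcomere list. This list had an adjusted p = 0.0117 with the preset correlation and an adjusted p = 0.448 with an estimated correlation, and its preset adjusted p was 0.0564 without overexpression replicate 2. The locus list had 1 higher and 3 lower without wild type replicates 1 or 2, 3 and 9 without overexpression replicate 1, 3 and 3 without overexpression replicates 2 or 4, and 5 and 3 with library totals only.

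Markers of atrial cardiomyocytes fell in 5 of 17 cases and rose in 0 (0 higher and 7 lower adjusted over the list alone), with a median of -0.45, or -0.11 (1 higher and 5 lower) when scaled to the sarcomere list. Myl7, the atrial myosin light chain, fell from 8483 ± 495 to 2095 ± 961 CPM (-2.02 ± 0.30, adjusted p = 0.00628). Sarcomere genes fell in 9 of 33 cases and rose in 0 (0 higher and 9 lower adjusted over the list alone, median -0.35), with a median of 0.02 (4 higher and 9 lower) when scaled to the list itself; among them were Nebl (-2.15 ± 0.20), Nexn (-1.04 ± 0.09), Csrp3 (-0.97 ± 0.14) and the chaperone Cryab (-1.21 ± 0.13). With the preset correlation the adjusted p was 4.22e-19 for the atrial markers and 5.41e-11 for the sarcomere. Both lists had an adjusted p = 0.190 with an estimated correlation. The sarcomere list had 1 higher and 9 lower with library totals only. Beside these lists, fibroblast markers had a median of 0.22, vascular endothelial markers -0.06, and smooth muscle and pericyte markers 0.50.

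Oxidative phosphorylation genes, which build the respiratory chain, fell in 7 of 38 cases and rose in 0. Adjusted over the list alone, 27 fell and 0 rose. The median was -0.36, or 0.01 (0 higher and 0 lower) with libraries scaled to the sarcomere list, so the decrease was about that of the sarcomere genes. Ndufs7 (-0.56 ± 0.10, adjusted p = 0.0158) and Sdha (-0.61 ± 0.11, adjusted p = 0.0182) fell. The adjusted p was 0.0904 without wild type replicate 2, 0.0685 without wild type replicate 3, 0.0867 with the replicate block and 0.300 with sarcomere scaling for Ndufs7, and 0.0609 without wild type replicate 1, 0.108 without wild type replicate 2, 0.0546 without wild type replicate 3, 0.0504 without overexpression replicate 3, 0.0612 with the replicate block and 0.154 with sarcomere scaling for Sdha. Fatty acid oxidation genes fell in 7 of 30 cases and rose in 0 (1 higher and 14 lower adjusted over the list alone, median -0.45), led by Acsl1, which activates fatty acids, from 707 ± 156 to 280.0 ± 18.6 CPM (-1.34 ± 0.15, adjusted p = 0.00161), and the fatty acid carrier Fabp3 (-1.09 ± 0.18, adjusted p = 0.0101). Their median became -0.07 (1 higher and 3 lower) when scaled to the sarcomere list. The tricarboxylic acid cycle list also holds genes of the pyruvate dehydrogenase complex. Its genes fell in 6 of 24 cases and rose in 0 (0 higher and 11 lower adjusted over the list alone). Among those that fell was Pdhx, of that complex (-0.97 ± 0.13, adjusted p = 0.00367). The median of this list, -0.30, became 0.06 (0 higher and 1 lower) when scaled to the sarcomere list. Adjusted p with the preset correlation was 1.49e-12, 2.79e-10 and 2.87e-08 for the 3 lists. They had an adjusted p = 0.307, 0.379 and 0.379 with an estimated correlation. Oxidative phosphorylation had 0 higher and 3 lower without wild type replicate 1 or overexpression replicate 4 or with library totals only, 0 and 0 without wild type replicates 2 or 3, 0 and 12 without overexpression replicate 1, 0 and 4 without overexpression replicate 2, and 0 and 2 without overexpression replicate 3. Fatty acid oxidation had 0 higher and 2 lower without wild type replicates 2 or 3, 1 and 7 without overexpression replicate 1, and 0 and 3 without overexpression replicate 3. The tricarboxylic acid cycle had 0 higher and 2 lower without wild type replicate 1 or overexpression replicate 2, 0 and 1 without wild type replicates 2 or 3 or overexpression replicate 3, and 0 and 3 with library totals only. Glycolysis was not called (adjusted p = 0.131), and in it Pfkp rose (1.25 ± 0.15, adjusted p = 0.00184) among 1 higher and 4 lower of 23 (2 higher and 6 lower adjusted over the list alone). Glycolysis had 1 higher and 1 lower without wild type replicates 1 or 3 or overexpression replicate 4, 1 and 0 without wild type replicate 2, 2 and 6 without overexpression replicate 1, 1 and 2 without overexpression replicates 2 or 3, and 2 and 2 with library totals only.

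Of the genes with the largest increases, several were near absent in wild type atria. Gpr83, a G protein-coupled receptor, rose from 0.160 ± 0.182 to 34.2 ± 14.7 CPM (7.54 ± 0.64, adjusted p = 5.01e-04). Gdnf, a neurotrophic factor with 0 wild type counts, was at least 14.5-fold higher against a floor of 3 counts over the group. Sftpa1, known as a lung surfactant protein, had 1 wild type count and 7.91 ± 3.14 CPM in overexpression, a ratio of 194 with a 95% counting interval of 34.5 to 7693. Ncan, Sel1l3 and Syndig1 had ratios of 76.6 (interval 25.96 to 374), 58.4 (15.9 to 487) and 22.99 (6.09 to 194). Frem3 rose by 5.61 ± 0.60 and Mstn, the muscle growth inhibitor myostatin, by 4.28 ± 0.60, from 1.59 ± 0.775 to 31.5 ± 16.9 CPM (adjusted p = 0.00633, or 0.0558 with limma-voom). Smaller increases with little spread were those of Pde1b (2.53 ± 0.21) and Abcc1 (1.03 ± 0.09). Among the largest decreases, Sds, serine dehydratase, fell from 48.1 ± 6.90 to 0.366 ± 0.168 CPM (-6.99 ± 0.24, adjusted p = 9.21e-07), Ptgfr, the prostaglandin F receptor, from 439 ± 28.3 to 26.6 ± 4.18 (-4.04 ± 0.13, adjusted p = 9.21e-07), and Lrrc2 from 111 ± 27.5 to 3.88 ± 1.34 (-4.83 ± 0.25, adjusted p = 2.56e-05). Log2 fold changes of other genes that fell were -4.63 ± 0.79 for Scd3 (adjusted p = 0.0122, or 0.0666 with the replicate block), -3.82 ± 0.34 for Bmp3, -3.61 ± 0.22 for Pirt, -2.90 ± 0.14 for Krt222 and -5.496 ± 0.25 for 5430419D17Rik. Cdcp1 and Rufy4 had 1 count each over the overexpression libraries, and wild type exceeded overexpression by ratios of 241 (42.8 to 9580.2) and 71.9 (12.4 to 2889).

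Smooth muscle and pericyte markers rose in 3 of 15 cases and fell in 0 (9 higher and 0 lower adjusted over the list alone, median 0.50). Acta2 and Cspg4 (1.34 ± 0.20, adjusted p = 0.00592) were among the 3, with Notch3 (0.62 ± 0.15, adjusted p = 0.0479 or 0.190 without wild type replicate 1, 0.149 without wild type replicate 2, 0.112 without wild type replicate 3, 0.0612 without overexpression replicate 2, 0.0859 without overexpression replicate 3, 0.0599 without overexpression replicate 4, 0.0564 with limma-voom, 0.0863 with the replicate block, 0.0539 with the Y-linked level as a covariate and 0.0758 in the female libraries). Extracellular matrix genes rose in 1 of 43 cases and fell in 0 (1 higher and 0 lower adjusted over the list alone, median 0.59), the riser being the collagen gene Col12a1 (2.90 ± 0.35, adjusted p = 0.00272). Of the 15 activated fibroblast markers, Acta2 alone passed the test (1 higher and 0 lower adjusted over the list alone). Their median was 0.67, and 0.46 without overexpression replicate 1, in which it was 1.84 against 0.21, 0.20 and 0.30 in the other overexpression libraries. Adjusted p with the preset correlation was 8.64e-08, 1.17e-07 and 0.00215. The 3 lists had an adjusted p = 0.190, 0.379 and 0.380 with an estimated correlation. The smooth muscle list had 7 higher and 0 lower without overexpression replicate 1, and 6 and 0 with library totals only. The matrix list had 2 higher and 0 lower without wild type replicate 3 or with library totals only, and 2 and 1 without overexpression replicate 1. The activated fibroblast list had 1 higher and 1 lower without overexpression replicate 1. Scaled to the sarcomere list, the medians were 0.87 (10 higher and 0 lower), 0.96 (13 higher and 0 lower) and 1.06 (1 higher and 0 lower), and the activated fibroblast list was not called (preset adjusted p = 0.142).

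Immediate early genes rose in 3 of 22 cases and fell in 0 (9 higher and 0 lower adjusted over the list alone, median 0.77). Fosb rose from 0.410 ± 0.238 to 5.11 ± 3.04 CPM (3.57 ± 0.59, adjusted p = 0.00980), and Jun by 1.01 ± 0.19 (adjusted p = 0.0198) and Fos by 1.80 ± 0.41 (adjusted p = 0.0492). The adjusted p of Jun was 0.0848 without wild type replicate 1, 0.108 without wild type replicate 2, 0.0650 without wild type replicate 3 and 0.0638 in the female libraries, and that of Fos 0.187 without wild type replicate 1, 0.209 without wild type replicate 2, 0.0953 without wild type replicate 3, 0.0829 without overexpression replicate 3, 0.0590 without overexpression replicate 4, 0.118 with no low-count filter, 0.0511 with CPM of at least 1 in 3 libraries, 0.0753 with limma-voom, 0.0867 with the replicate block and 0.0835 in the female libraries. Interferon response genes rose in 2 of 25 cases and fell in 0 (2 higher and 0 lower adjusted over the list alone, median 0.79), Rsad2 (1.83 ± 0.26, adjusted p = 0.00446) and Ifit2 (1.15 ± 0.23, adjusted p = 0.0256, or 0.112 without wild type replicate 2, 0.0987 without wild type replicate 3, 0.0650 without overexpression replicate 2, 0.0589 without overexpression replicate 4 and 0.0735 with the replicate block). Library medians for that list were -0.05, 1.51, 0.85 and 1.45 in overexpression replicates 1 to 4, and 0.71 in wild type replicate 1. Adjusted p with the preset correlation was 1.11e-07 for immediate early and 1.01e-05 for interferon genes. They had an adjusted p = 0.321 and 0.556 with an estimated correlation. The immediate early list had 1 higher and 0 lower without wild type replicates 1, 2 or 3, 7 and 0 without overexpression replicate 1, and 8 and 0 with library totals only. The interferon list had 1 higher and 0 lower without wild type replicate 2 or overexpression replicates 2 or 4, 1 and 1 without wild type replicate 3, and 7 and 0 without overexpression replicate 1. Without overexpression replicate 1 the preset adjusted p of the interferon list was 8.62e-09. Scaled to the sarcomere list, the medians were 1.14 (14 higher and 0 lower) and 1.18 (5 higher and 0 lower), where 2508 of all 13295 tested genes were called higher. Sinoatrial node markers rose in 2 of 9 cases, Hcn4 among them, and fell in 1, Cacna2d2 (2 higher and 1 lower adjusted over the list alone; preset adjusted p = 0.00685, or 0.0605 when scaled to the sarcomere list, where the median of 0.25 was 0.62 (2 higher and 1 lower), and adjusted p = 0.307 with an estimated correlation).

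The cell cycle list was called higher with the preset correlation (adjusted p = 0.00250), yet 0 of its 28 members passed the edgeR test, by DESeq2 also 0, adjusted over the list alone 0, and 1 had an unadjusted p under 0.05. It had an adjusted p = 0.759 with an estimated correlation. The median of 1.34 came from overexpression replicate 1, where list members stood at 2.77 against 0.11, 0.29 and 0.07 in the other 3, and it was 0.20 without that library. The cell cycle list was then no longer called (preset adjusted p = 0.229). Thyroid hormone responsive genes fell in 4 of 19 cases and rose in 0 (0 higher and 5 lower adjusted over the list alone), with a test direction of lower (preset adjusted p = 0.00956), a mean of -0.25 and a median of 0.05 of opposite sign. It had an adjusted p = 0.380 with an estimated correlation, and a preset adjusted p of 0.174 without overexpression replicate 1. The thyroid list had 0 higher and 2 lower without wild type replicates 2 or 3. Endocardial markers fell in 1 of 6 cases, Tmem108 (-0.72 ± 0.15, adjusted p = 0.0281), and rose in 0 (0 higher and 3 lower adjusted over the list alone). Macrophage markers rose in 1 of 20, Trem2 (1.47 ± 0.35, adjusted p = 0.0464), and fell in 0 (1 higher and 0 lower adjusted over the list alone). Schwann cell and neuron markers rose in 1 of 8, Mbp (0.47 ± 0.11, adjusted p = 0.0432), and fell in 0 (2 higher and 0 lower adjusted over the list alone). The adjusted p was 0.119 without wild type replicate 1, 0.136 without wild type replicate 2, 0.0716 without overexpression replicate 2, 0.0754 without overexpression replicate 3, 0.0722 without overexpression replicate 4, 0.0539 with library totals only, 0.0631 with the replicate block and 0.155 with sarcomere scaling for Tmem108, 0.180 without wild type replicate 1, 0.189 without wild type replicate 2, 0.0825 without overexpression replicate 2, 0.0769 without overexpression replicate 3, 0.0732 without overexpression replicate 4, 0.0913 with the replicate block, 0.0525 with the Y-linked level as a covariate, 0.115 in the female libraries and 0.0529 with the length and GC offset for Trem2, and 0.163 without wild type replicate 1, 0.118 without wild type replicate 2, 0.136 without wild type replicate 3, 0.0711 without overexpression replicate 2, 0.102 without overexpression replicate 4 and 0.148 with the replicate block for Mbp. Their preset adjusted p was 0.00471, 0.0430 and 0.0430, and they had an adjusted p = 0.359, 0.693 and 0.379 with an estimated correlation. The endocardial list had 0 higher and 0 lower without wild type replicates 1 or 2 or overexpression replicates 2, 3 or 4 or with library totals only, and 0 and 4 without overexpression replicate 1. The macrophage list had 0 higher and 0 lower without wild type replicates 1 or 2 or overexpression replicates 2, 3 or 4. The Schwann cell list had 0 higher and 0 lower without wild type replicates 1, 2 or 3 or overexpression replicates 2 or 4, 3 and 0 without overexpression replicate 1, and 2 and 0 with library totals only. The preset adjusted p of the macrophage list was 0.344 without wild type replicate 3, 0.167 without overexpression replicate 1 and 0.223 without overexpression replicate 2, and that of the Schwann cell list 0.0643 without wild type replicate 1, 0.132 without wild type replicate 2, 0.0850 without wild type replicate 3, 0.124 without overexpression replicate 2 and 0.0655 without overexpression replicate 4. Medians of the 5 lists went from 1.34, 0.05, -0.40, 0.24 and 0.39 to 1.74 (1 higher and 0 lower), 0.41 (2 higher and 3 lower), -0.02 (0 higher and 0 lower), 0.63 (8 higher and 0 lower) and 0.76 (3 higher and 0 lower) when scaled to the sarcomere list.

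**Figure D4:**
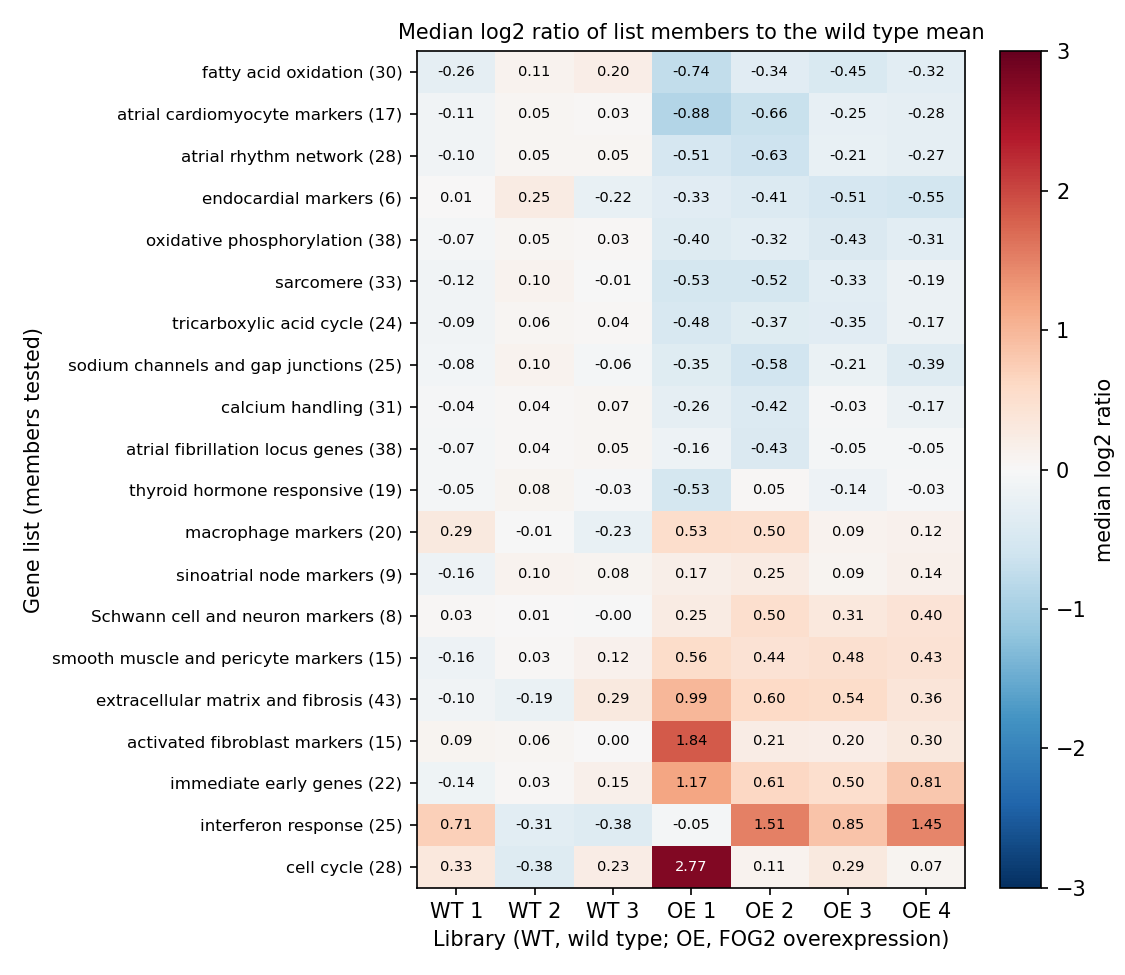
Median log2 ratio of list members to the wild type mean in each library, for the 20 lists called with camera's preset correlation; rows are lists with the number of members tested, columns are libraries. The cell cycle list stood at 2.77 in overexpression replicate 1 and at 0.07 to 0.29 in the other overexpression libraries, while the atrial rhythm network lay between -0.63 and -0.21 in all 4.

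Of 43 lists tested, 20 were called with the preset correlation, 9 higher and 11 lower. With an estimated correlation camera called 0, where 6 had an unadjusted p under 0.05 and the smallest adjusted p was 0.190, and fry, which asks whether members move one way, called 9. Fry gave an adjusted p = 0.00963 for the atrial rhythm network, atrial cardiomyocyte markers, sarcomere and oxidative phosphorylation. Sodium channels and gap junctions and the smooth muscle and pericyte markers had that value too. Its other calls were sinoatrial node markers (0.0183), tricarboxylic acid cycle (0.0272) and endocardial markers (0.0272). In 13 of the 35 ways to split the 7 libraries into 4 and 3, the real one included, the preset correlation called 20 lists or more.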

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

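The tests of sex, mislabelling, smooth muscle cells and activated fibroblasts were chosen after the results were seen, as were those of cardiomyocyte share and of transcript length and GC content; that of chance was not. In the 4 overexpression libraries, 22 of 187 named genes had 1 library far from the other 3 by Dixon's ratio, where chance gives about 1 in 20, or 9.35. For the 2 of them with a single count in all, Cdcp1 and Rufy4, the ratio is 1 whichever library holds it, so it says nothing; among genes with counts in at least 2 of these libraries it was 20 of 185, where chance gives 9.25. Wild type, with 3 libraries, was not tested. Replicate 1 was the distant library for 15 of the 22, given as its CPM with the range of the other 3: Nppb at 168 (6.96 to 19.6), Lox at 63.5 (19.8 to 25.6), Dio2 at 114 (8.18 to 14.2), Mcm5 at 70.4 (10.8 to 12.7), Bub1 at 10.996 (0.815 to 2.09), Ccna2 at 39.8 (2.21 to 5.39), Bhlhe40 at 88.7 (60.02 to 64.00), Krt19 at 76.2 (24.7 to 30.9), Upk1b at 96.7 (28.5 to 39.1), Krt8 at 24.8 (3.61 to 3.72), Slc4a1 at 21.3 (1.16 to 2.78), Fosb at 9.66 (3.47 to 3.84), Ccl7 at 17.7 (1.16 to 3.03), Trem2 at 7.33 (4.31 to 4.62) and Ccl25 at 1.89 (1.22 to 1.30). In replicate 2 they were Myl2 at 45.3 (0 to 1.39), Pck1 at 36.5 (0 to 0.522) and Cdcp1 at 0.144 (0 to 0). In replicate 3 they were Rufy4 at 0.174 (0 to 0), 5430419D17Rik at 0.174 (0.433 to 0.465) and Sdhb at 389.7 (429 to 434), and in replicate 4 Adm at 15.5 (10.7 to 11.2). Reads counted as ambiguous, which enter no gene's count, made up 0.254% of reads in overexpression replicate 1 and 0.101% to 0.168% in the other 6 libraries.

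Overexpression replicate 1 stood apart from the other overexpression libraries by more than 2-fold at 608 genes, 351 higher and 257 lower, where replicates 2, 3 and 4 did so at 55, 70 and 58. Sex was tested first, because replicate 1 and wild type replicate 2 were the 2 libraries with Y-linked transcripts: the 608 genes moved by a median of 1.75 on the log2 scale in replicate 1 and by -0.18 in that direction in wild type replicate 2, which argues against sex alone. A mislabelled wild type library was argued against by Zfpm2, at 140.1 CPM in it and at most 31.7 in wild type; that test replaced a first one, whose 73.3% of the 1151 genes called without it lying nearer to the overexpression mean left the question undecided. A difference between animals in their response to FOG2 was not tested and stays open.

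Within the rhythm network, 9 genes were called lower. A lower share of cardiomyocytes in the tissue would lower them together with the sarcomere, so the libraries were scaled to the sarcomere list. Of the 9, 8 stayed called lower, so these fell by more than the median of the sarcomere genes. That argues against a lower share as the whole cause for those 8. The 9 were chosen for their decreases in these same libraries, and the sarcomere genes themselves fell unevenly. The scaling still took 0.35 to 0.37 off each decrease: Ryr2 went from -1.13 ± 0.17 to -0.77 ± 0.13, and Slc8a1, the smallest kept, from -0.90 ± 0.15 to -0.54 ± 0.14. The median of the 9 went from -1.21 to -0.85, and that of all 28 genes of the list from -0.43 to -0.08, so a lower share stays open for part of each decrease and for most of the list's median. The exception, Kcnq1, named after its value was seen, went from -0.59 ± 0.13 to -0.22 ± 0.16 (SE), a call that ended because its fold shrank, and there a lower share stays open. With an offset for transcript length and GC content, 9 of the 9 stayed called lower, which argues against those. An effect of FOG2 on these genes in cardiomyocytes was not itself tested. It remains a hypothesis, drawn from the same libraries that these tests used.

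Acta2 rose by 5.05 ± 0.33 on the log2 scale. More smooth muscle cells would raise alike the other contractile markers that come mainly from that type. Of the 5, Tagln stood at 2.12 ± 0.51, Cnn1 at 1.29 ± 0.40 and Myh11 at 1.26 ± 0.42, with adjusted p of 0.0584, 0.115 and 0.151, and Mylk and Smtn at 0.50 ± 0.12 and -0.18 ± 0.10. Their median was 1.26, with an interquartile range of 0.79. In CPM, Acta2 went from 24.1 to 798, Tagln from 9.02 to 38.9 and Myh11 from 14.7 to 35.4. Mylk and Smtn stood at 33.0 and 137 CPM in wild type, above Acta2, so they may not track that type. Tagln, Cnn1 and Myh11 also had smaller log2 fold changes than Acta2, and for Cnn1 and Myh11 the groups overlapped. Cnn1, low throughout, had 1.39 CPM in overexpression replicate 3 and up to 1.41 in wild type. Myh11 had 15.33 CPM in overexpression replicate 1 and up to 20.94 in wild type. This test of the 5 contractile markers replaced a first one that pooled them with 9 pericyte and vessel wall markers. The median was 0.33 for those 9 and 0.43 over all 14. Activated fibroblasts would do so for their list, whose other markers had a median of 0.26 without overexpression replicate 1, where Acta2 stood at 4.90. Both values argue against these cells as the whole cause of a rise of that size. Some increase in smooth muscle cells stays open, since Tagln, Cnn1 and Myh11 had positive folds. A rise of Acta2 within cells already present was not tested and remains open.

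Chance was weighed by fitting all 35 splits of the 7 libraries into 4 and 3. Only the real split gave as many genes higher (1 of 35, with 206 against 10 in the highest other split), lower (1 of 35, with 438 against 26) or changed at least 2-fold (1 of 35, with 313 against 35). With 7 libraries 1 of 35 is the smallest share there can be, and it argues against chance for these counts. For gene lists chance cannot be set aside: 13 of the 35 splits called 20 lists or more with the preset correlation, up to 29. By this comparison the number of lists called did not stand out. The comparison is limited, since some other splits keep part of the real group difference. The split with 29 lists set the wild type libraries and overexpression replicate 3 against the other overexpression libraries.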

How the results depend on the processing

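Settings other than those named as added were fixed beforehand; the female libraries, sarcomere scaling and length and GC offset were added after the data were seen. Zfpm2 kept its direction and its call in all 22 alternatives, at log2 fold changes of 2.71 to 3.18. Of 80 named genes that were called, 80 kept their direction in the 22 alternatives and 50 their call in each; of the 108 others, 59 passed in at least 1. Against 206 higher and 438 lower, DESeq2 gave 437 and 674, 1 surrogate variable 537 and 715, library totals only 444 higher (294 lower), and sarcomere scaling 2508 and 215 with 584 genes at least 2-fold changed instead of 313 and a median log2 fold change of all genes of 0.39; the causes were not tested, except that sarcomere scaling and library totals only lift genes together by construction. Replicate numbers were shared by the groups as a name only: same-numbered libraries deviated together at r = 0.0789, 0.0136 and 0.0720, none over 0.1, and not every library correlated best with its own number; the replicate block gave 129 higher and 253 lower. Leaving out 1 library at a time gave 75 to 493 higher, 181 to 658 lower, 184 to 431 genes changed at least 2-fold and 18 to 28 lists; the gene counts grew only without overexpression replicate 1, and the cause was not tested. Of the 20 lists, 0 were called with an estimated correlation and 9 by fry; the cell cycle list reversed in the test in the female libraries (median 0.0648). Genes that did not pass the test turned sign as follows. The turns with sarcomere scaling (Gja1 0.16, Sod2 0.0210, Prdx5 0.0879, Cox7a1 0.26, Dbp 0.0479, Cd4 0.29, Actn3 0.13, Fabp4 0.10 and Pparg 0.00628) and with library totals only (Cox7a1 0.0167 and Cd4 0.0418) followed from the shift of all genes, whose median went from 0.02 to 0.39 and to 0.15, and say nothing about these genes. The cause was not tested for the others: in the female libraries Upk1b -0.0515, Slc9a3r1 -0.0614, Krt8 -0.31, Cd4 0.70, Actn3 0.00258 and Ccl25 -0.31; with 1 surrogate variable Krt8 -0.0558, Cd4 0.15, Xist -0.28 and Ccl25 -0.0635; with the replicate block S100a8 -0.0919 and Csf3r -0.15; with limma-voom Pck1 -0.14. With 1 library left out, ranges that crossed 0 were Cox7a1 -0.22 to 0.00382 (turned without overexpression replicate 1), Krt8 -0.23 to 1.33 (turned without overexpression replicate 1), Cd4 -0.32 to 0.42 (turned without wild type replicate 2 and overexpression replicate 1), S100a8 -0.11 to 0.87 (turned without overexpression replicate 4), S100a9 -0.0704 to 0.57 (turned without wild type replicate 2), Csf3r -0.10 to 0.65 (turned without overexpression replicate 4), Xist -0.27 to 0.92 (turned without wild type replicate 2), Actn3 -0.53 to 0.18 (turned without wild type replicate 2) and Ccl25 -0.13 to 0.45 (turned without wild type replicate 2 and overexpression replicate 1). With the depth of 5562520 to 8655655 counts and the spread between libraries, 20.9% of simulated 1.5-fold changes were recovered. That share also depends on the number of changed genes, set at 200 in the simulation, and on genes being drawn independently there.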

Other observations

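The looks at single genes of other tissues and at replicates 1 and 2 were chosen after the results were seen, and the lists were not. Several lists that were not called as a whole held single genes that changed. In angiogenic signalling, Angpt1, a ligand of the endothelial receptor Tek, fell from 689 ± 75.6 to 76.5 ± 30.4 CPM (-3.17 ± 0.27, adjusted p = 4.74e-04), while its relative Angpt2 rose (1.28 ± 0.19, adjusted p = 0.00559); 2 of 28 higher and 1 lower passed (3 higher and 3 lower adjusted over the list alone, list adjusted p = 0.586). Among autonomic receptors and signalling genes, 2 of 24 higher and 1 lower passed (3 higher and 2 lower adjusted over the list alone, list adjusted p = 0.280), and Adora1, an adenosine receptor, rose from 13.2 ± 2.27 to 38.3 ± 9.93 CPM (1.53 ± 0.22, adjusted p = 0.00559). In the hypertrophic stress programme 0 of 23 higher and 2 lower passed (7 higher and 3 lower adjusted over the list alone, list adjusted p = 0.263); Ankrd1 fell (-1.97 ± 0.39, adjusted p = 0.0288), with an adjusted p of 0.0932 without wild type replicate 1, 0.130 without wild type replicate 2, 0.0653 without wild type replicate 3, 0.0571 without overexpression replicate 2, 0.0530 without overexpression replicate 4, 0.0754 with no low-count filter and 0.0526 with sarcomere scaling, as did Ankrd23 (-1.26 ± 0.23, adjusted p = 0.0161), with an adjusted p of 0.0511 without wild type replicate 1, 0.0556 without wild type replicate 2, 0.0650 without wild type replicate 3, 0.0532 without overexpression replicate 3, 0.0562 in the female libraries and 0.0523 with sarcomere scaling. Angiogenic signalling had 1 higher and 1 lower without wild type replicates 1, 2 or 3 or overexpression replicate 4, and 2 and 4 without overexpression replicate 1. The autonomic list had 1 higher and 0 lower without wild type replicates 1, 2 or 3 or overexpression replicate 3, 3 and 2 without overexpression replicate 1, 1 and 1 without overexpression replicate 4, and 3 and 0 with library totals only. The stress programme had 0 higher and 0 lower without wild type replicates 1, 2 or 3, 5 and 3 without overexpression replicate 1, 1 and 1 without overexpression replicates 2 or 4, 3 and 1 without overexpression replicate 3, and 6 and 2 with library totals only. In the p53 and apoptosis list, Ccng1 fell from 1265 ± 35.7 to 716 ± 63.5 CPM (-0.82 ± 0.11, adjusted p = 0.00360), the only member of 24 past the threshold over all genes (0 higher and 2 lower adjusted over the list alone, list adjusted p = 0.896).

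Other uncalled lists with members past the test were ventricular cardiomyocyte markers (0 higher and 1 lower of 6, 0 and 2 adjusted over the list alone, list adjusted p = 0.0558), inflammatory cytokines and chemokines (1 higher and 0 lower of 17, 3 and 0 adjusted over the list alone, list adjusted p = 0.0668), antioxidant and NRF2 response (0 higher and 1 lower of 23, 0 and 1 adjusted over the list alone, list adjusted p = 0.206), heat shock and proteostasis (0 higher and 3 lower of 22, 1 and 4 adjusted over the list alone, list adjusted p = 0.277), endoplasmic reticulum stress (0 higher and 1 lower of 26, 1 and 3 adjusted over the list alone, list adjusted p = 0.490). Inflammatory cytokines and chemokines had 0 higher and 0 lower without wild type replicates 1, 2 or 3 or overexpression replicates 2 or 3, 2 and 0 without overexpression replicate 1, and 3 and 0 with library totals only. Antioxidant and NRF2 response had 0 higher and 2 lower without overexpression replicate 1. Heat shock and proteostasis had 0 higher and 1 lower without wild type replicate 2, 0 and 5 without overexpression replicate 1, and 1 and 2 with library totals only. Endoplasmic reticulum stress had 0 higher and 0 lower without wild type replicates 1 or 2 or overexpression replicate 2, 1 and 1 without overexpression replicate 1 or with library totals only, and 1 and 0 without overexpression replicate 3. P53 and apoptosis had 1 higher and 2 lower without overexpression replicate 1. Without that library the list of ventricular markers was called lower (preset adjusted p = 0.0299). No member passed the edgeR test in the remaining 11 uncalled lists; members with an unadjusted p under 0.05, and members DESeq2 called, numbered 3 and 2 of 6 for lymphatic endothelial markers (adjusted p = 0.0568), 5 and 0 of 15 for fibroblast markers (adjusted p = 0.0668), 0 and 0 of 11 for epicardial and mesothelial markers (adjusted p = 0.131), 4 and 1 of 19 for circadian clock (adjusted p = 0.131), 2 and 0 of 23 for ribosomal proteins (adjusted p = 0.131), 0 and 0 of 10 for white adipocyte markers (adjusted p = 0.490), 2 and 0 of 19 for vascular endothelial markers (adjusted p = 0.597), 2 and 0 of 17 for glucocorticoid responsive (adjusted p = 0.597), 0 and 0 of 7 for non-polyadenylated and structural RNAs (adjusted p = 0.626), 1 and 1 of 5 for neutrophil and mast cell markers (adjusted p = 0.719), 1 and 0 of 7 for skeletal muscle markers (adjusted p = 0.851). Lymphatic endothelial markers had 2 higher and 0 lower without wild type replicate 3, and 1 and 0 without overexpression replicate 1 or with library totals only. Circadian clock had 0 higher and 1 lower without wild type replicate 3, and 0 and 2 without overexpression replicate 1. The fibroblast marker list was called higher without overexpression replicate 1 (preset adjusted p = 0.0137, median 0.30). White adipocyte markers had 0 higher and 1 lower without overexpression replicate 1. Vascular endothelial markers had 0 higher and 1 lower without overexpression replicate 1. Neutrophil and mast cell markers had 0 higher and 1 lower without wild type replicate 3 or overexpression replicate 1. Skeletal muscle markers had 1 higher and 0 lower without overexpression replicate 1.

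The test direction and the median or mean differed in sign for these uncalled lists: ventricular markers (lower; median -0.34, mean 0.23), white adipocyte markers (lower; -0.11 and 0.27), neutrophil and mast cell markers (lower; 0.28 and -0.11), skeletal muscle markers (lower; 0.13 and 0.02) and p53 and apoptosis (lower; 0.17 and 0.04). Some marker genes of ventricle and fat were highest in overexpression replicate 2, with Myl2 at 45.3 CPM against 0 to 1.39 elsewhere, Pck1 at 36.5, Adipoq at 17.5 (at most 4.80 elsewhere) and Ucp1 at 15.02. Others were not: Myh7 was lowest there, at 715 CPM, and Fabp4 stood at 201 against 315 in replicate 1. Sftpa1 had 67, 44, 31 and 107 counts in the overexpression libraries, while Sftpc, a more lung-restricted surfactant gene, had 0 in all 7 and Scgb1a1 had 1 in a single wild type library. Overexpression replicate 1 held Mki67 at 146 CPM and Postn at 599, against means of 12.2 and 70.6 in the other 3 overexpression libraries and 10.8 and 82.1 in wild type.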
